A study of Mus musculus with 8 samples.

How the data were processed

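RNA from type 7 to 8 ovarian follicles (a morphological stage) of Kunming mice, an outbred stock, was profiled at postnatal day 21, 24 hours after injection of pregnant mare serum gonadotropin (PMSG, a hormone that acts like follicle-stimulating hormone, FSH). Control samples received PMSG with saline and melatonin samples received PMSG with melatonin, with 4 samples in each group, per the labels. The labels give replicate numbers but do not say whether replicates came from separate animals or from pools, so p-values measure the spread between these samples, which may be technical in part.

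Per the labels' protocols, follicles were frozen after isolation, total RNA was extracted with Trizol, and libraries were made with a NEBNext Ultra RNA kit. The authors aligned reads with HISAT2 2.0.5 to mm10, per the submitters' processing notes. The counting tool, annotation, adapter trimming and use of strand are not given in the sources used here. The deposited values are FPKM (fragments per kilobase of exon, scaled to the mapped fragments of each library) per gene, per the file headers. FPKM is divided by gene length and by library total, so it is relative to the other genes of a library and cannot show a change in total RNA per follicle. A table of the whole series, named as transcript values, held 55157 genes with 0 cells differing from the 8 sample files. It therefore served as a check, and no transcript-level comparison was made.

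Depth was estimated from the FPKM values themselves. With exon lengths from GENCODE M21 (mm10), which matched 54495 of the 55157 identifiers, 98.8% of low values were whole numbers of fragments within 0.05 fragments, over values of up to 30 fragments. The implied number of fragments assigned to genes was 17451090 to 22034286 in the control libraries and 18553165 to 23649176 in the melatonin libraries. At these depths 1 fragment on a gene of 1 kb was worth between 0.042 and 0.057 FPKM. Coordinates are mm10 positions from GENCODE M21.

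Because the values are FPKM and not counts, genes were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend) on log2(FPKM + 1). Fold changes are on this scale, which understates the change of genes with low values. The 14738 genes with a mean of at least 1 FPKM over the 8 libraries were tested, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. All 8 samples entered the fit with group as the single term. Gene lists were fixed before the data were examined. Of 36 lists, the 34 with at least 5 tested members were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. A list score is the mean over members of log2(FPKM + 1), after centring each gene on its mean over the 8 libraries. Differences in single scores were tested by a two-sided exact permutation test over the 70 assignments of 8 samples to the groups, whose smallest p is 0.0286.

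The genes named in the text follow a rule set before the data were examined. It took up to 12 genes in each direction past the threshold (there were none), a panel of 19 genes on FSH response, steroid synthesis, melatonin and metabolism, the 2 members of each list with the smallest p, and, as fewer than 10 genes passed, the 8 genes in each direction with the smallest unadjusted p. Some genes that the rule takes are not reported here. Other genes were chosen after their values were seen, which is said where they are named.

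The gene test was checked on simulated data with 200 of 14738 genes changed in the comparison of melatonin with control. It recovered 59.7% of genes changed by 0.5 on the log2 scale, 80.6% of those changed by 1 and 98.5% of those changed by 2, and called 11 unchanged genes. Simulated genes were drawn independently of each other, unlike the real ones. The list test was run on 34 lists in each of 100 simulated draws without an effect, and made 9 calls in total over all draws. Genes were independent in these draws too, so they cannot check the preset correlation.

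Alternatives set before the data were examined were quantile normalization, filters of 0 and 5 FPKM, a pseudocount of 0.1, array weights, other thresholds, the replicate number as a block, leaving out each of the 8 libraries, an estimated inter-gene correlation and fry. After the data were seen, limma-voom on the 13761 tested genes with recovered fragment counts, median-ratio scaling, removal of GC content and exon length trends (natural splines with 5 degrees of freedom in each library) and an exact permutation test of the list scores were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.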

Results

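The series measured messenger RNA in mouse type 7 to 8 follicles 24 hours after PMSG given with saline (control) or with melatonin, in 4 libraries per group. Its title places melatonin downstream of FSH and concerns nutrient accumulation and mitochondrial function in oocytes, so the single comparison of the design asks how melatonin given with the gonadotropin changes follicular transcripts. The implied depth was 17451090 to 22034286 assigned fragments in control and 18553165 to 23649176 in melatonin libraries. Between 14504 and 14833 genes per library reached 1 FPKM.

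Granulosa transcripts were abundant, with Inha (inhibin alpha) at 6597 ± 641 FPKM in control and 5445 ± 309 FPKM in melatonin follicles, and the oocyte gene Gdf9 was present at 107 ± 19.1 and 97.9 ± 14.3 FPKM (SD, n = 4 each). Pearson correlations of log2(FPKM + 1) over the 14738 tested genes were 0.969 to 0.976 within control, 0.975 to 0.980 within melatonin and 0.961 to 0.977 between the groups. The first principal component held 26.5% of the variance. Its scores ran from -29.9 to -0.49 in control and from 5.81 to 17.4 in melatonin libraries, with control replicate 3 at the low end. GC content and length dependence of the libraries also separated the groups. The Spearman correlation across genes, which are not independent replicates, of a library's deviation from the mean with GC content was -0.02 to 0.26 in control and -0.18 to -0.12 in melatonin libraries. That with exon length was -0.107 to -0.048 in control and 0.024 to 0.115 in melatonin libraries (two-sided exact permutation p = 0.0286 for each).

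**Figure D1:**
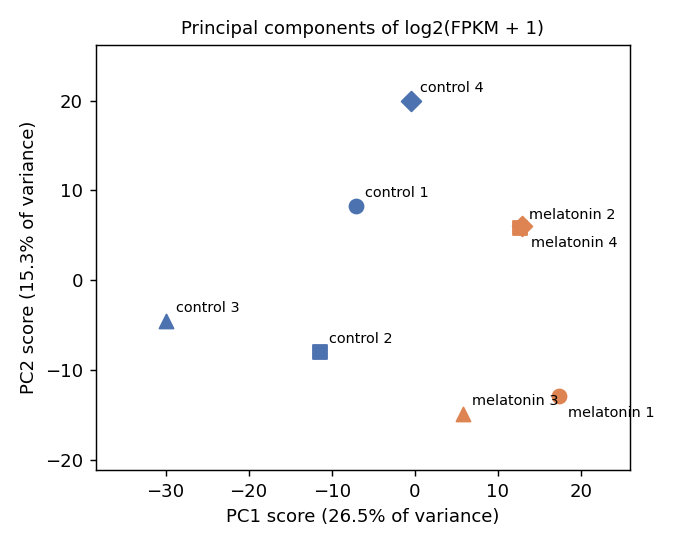
Scores of the 8 libraries on the first 2 principal components of log2(FPKM + 1) (arbitrary units), one point per library, blue for control and orange for melatonin, with the marker shape giving the replicate number. The first component (26.5% of variance) runs from -29.9 in control replicate 3 to 17.4 in melatonin replicate 1.

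No single gene passed the threshold. With limma, 0 of 14738 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.120. An unadjusted p under 0.05 was found for 2821 genes, 1385 higher and 1436 lower with melatonin, where 737 would be expected by chance. The 4 melatonin values lay entirely above or below the 4 control values in 1728 genes, or 11.7% of those tested, where chance gives 2.86%. limma-voom on recovered fragment counts also called 0 genes, with 2739 at an unadjusted p under 0.05. That fit left out genes without recovered counts. Among the genes named below these were Fshr, Lhcgr, Cyp17a1, Cpt1a, Scd1, Scd2, Ndufs8 and Cd74, which lie on chromosomes 17, 18 and 19.

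Among the genes with the smallest unadjusted p, given as values that did not pass, 4 higher ones code for known proteins. Ank, a pyrophosphate transporter (chromosome 15, 27466677 to 27594909), was at 7.44 ± 0.67 FPKM in control and 11.03 ± 0.58 in melatonin. Ppm1e, a protein phosphatase, was at 4.85 ± 0.42 and 7.15 ± 0.44. Cald1, caldesmon, was at 11.6 ± 0.76 and 16.3 ± 1.14. Clk1, a kinase of splicing factors, was at 40.8 ± 3.37 and 56.6 ± 3.30 (SD, n = 4 each). The other higher ones were the pseudogene Gm47052 and the small or unclassified transcripts Gm22770, Gm43980 and Gm23908, with log2 fold changes from 0.47 to 1.25. On the lower side, Uck2, a uridine-cytidine kinase (chromosome 1, 167222883 to 167285320), had 16.6 ± 0.955 FPKM in control and 12.1 ± 0.46 in melatonin. Nup210, a nuclear pore protein, had 12.2 ± 0.60 and 9.05 ± 0.26, and Dbi, the acyl-CoA binding protein, had 44.1 ± 1.00 and 35.7 ± 1.64. Socs3, a feedback inhibitor of cytokine signalling, had 13.0 ± 1.27 and 7.70 ± 1.18, and Btg2, an antiproliferative immediate-early gene, had 45.0 ± 5.44 and 28.5 ± 3.46. Sdhaf4, an assembly factor of succinate dehydrogenase, the pseudogene Gm3756 and the small nucleolar RNA Gm25604 had log2 fold changes of -0.33, -0.27 and -1.08. All 16 had an adjusted p of 0.120 and no overlap between the groups. Gm22770 rested on 14 recovered fragments over the 4 control libraries and Gm25604 on 15 over the 4 melatonin libraries. Gm47052 and Gm3756 are processed pseudogenes that can share reads with their parent genes, so their values are uncertain.

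Of the 34 gene lists tested, 22 were lower with melatonin relative to all other genes and 0 were higher (camera, adjusted p under 0.05 with the preset correlation). With a correlation estimated from the data none of the 22 kept its call, the smallest adjusted p being 0.307 with an estimated correlation. In 7 lists the scores of the groups did not overlap, which gives the smallest exact permutation p the design allows (0.0286). These were steroid synthesis, theca markers, fatty acid oxidation, glycolysis, TCA cycle, oxidative phosphorylation and antioxidant enzymes. Adjusted over the 34 lists that p is 0.139. At least 20 lists would have to reach the smallest p before any could pass, so the adjusted exact test could not keep a call here. No list had a member past the threshold over all genes, so member counts are given adjusted over the list alone. The lists share some members, such as Cyp11a1, Cyp17a1 and Hsd17b1. Genes with higher values leaned lower in general. With a filter of 5 FPKM, 1217 genes were lower and 789 higher at an unadjusted p under 0.05 (limma). FPKM summed over genes was 287731 to 302290 in control and 278096 to 284604 in melatonin libraries. Part of the one-way direction may therefore not be particular to these lists. With that filter 13 of 30 lists were called, all lower (camera, preset correlation). Ranges of adjusted p given with a changed call are over up to 14 alternative settings of the test with the preset correlation, 8 of which leave out 1 library. Scores of 688 antisense, sense intronic and unclassified (TEC) transcripts, grouped after their values were seen, separated the groups in the other direction, from -0.137 to -0.047 in control and from 0.064 to 0.104 in melatonin libraries (exact permutation p = 0.0286).

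**Figure D2:**
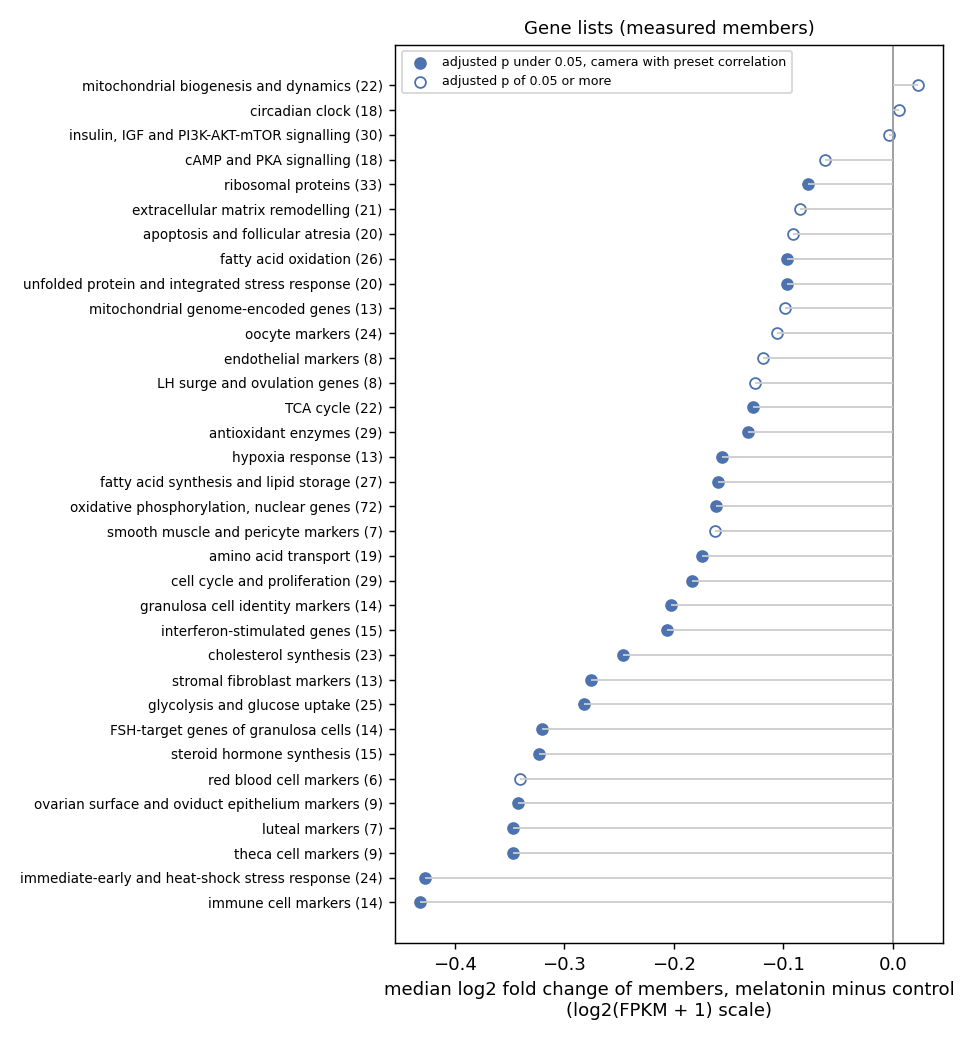
Median log2 fold change (melatonin minus control, log2(FPKM + 1) scale) of the tested members of each of 34 gene lists, with the number of members in parentheses and filled points for the 22 lists with an adjusted p under 0.05 by camera with the preset correlation. Medians run from -0.43 for immune cell markers to 0.02 for mitochondrial biogenesis and dynamics.

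FSH-target genes were lower with melatonin as a list. All 8 samples received PMSG, so levels of these transcripts were compared and not a response to FSH. Of 14 measured FSH-target genes of granulosa cells 12 had a negative log2 fold change (median -0.32; camera adjusted p = 0.00334 and adjusted p = 0.308 with an estimated correlation), and 1 passed adjusted over the list alone, Hsd17b1, which makes estradiol from estrone. Hsd17b1 (chromosome 11, 101078411 to 101080527) had 407 ± 74.3 FPKM in control and 265 ± 37.3 in melatonin (SD, n = 4 each). Inhibin beta subunits had 347 ± 128 against 170 ± 80.5 FPKM for Inhba (log2 fold change -1.06 ± 0.34 SE, adjusted p = 0.169). The values were 803 ± 260 against 437 ± 158 for Inhbb. Cyp19a1, aromatase (chromosome 9, 54165937 to 54268110), had 11.4 ± 8.29 against 4.31 ± 3.30 FPKM (log2 fold change -1.16 ± 0.50 SE, adjusted p = 0.256). The highest Cyp19a1 values were 23.0 in control replicate 3 and 9.25 in melatonin replicate 3, and without control replicate 3 the log2 fold change was -0.76. The FSH receptor gene Fshr (chromosome 17, 88984952 to 89200675) had 59.2 ± 8.43 against 43.6 ± 6.53 FPKM. The LH receptor gene Lhcgr had 3.66 ± 1.04 against 2.19 ± 1.32. Ccnd2, a cyclin of granulosa proliferation, had 37.2 ± 6.73 against 31.4 ± 4.95. Granulosa cell identity markers were lower in 12 of 14 (camera adjusted p = 0.0049 and adjusted p = 0.308 with an estimated correlation), with 4 past the threshold adjusted over the list alone (Hsd17b1, Fshr, Bex2 and Gata4, the last 2 named after their values were seen). The call was lost after quantile normalization, where the mean log2 fold change was -0.126 in place of -0.199 (adjusted p = 0.0832, range 0.00105 to 0.0832).

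Steroid hormone synthesis was lower as a list, with 13 of 15 members negative (median -0.32; camera adjusted p = 0.00134 and adjusted p = 0.308 with an estimated correlation) and 5 lower adjusted over the list alone. These were Hsd17b1, Scarb1 (a lipoprotein receptor for cholesterol uptake, 28.2 ± 4.93 against 20.8 ± 2.71 FPKM), Cyp11a1, Cyp17a1 and Nr5a1, the last named after its values were seen. Cyp11a1, which cleaves the cholesterol side chain, had 18.6 ± 4.67 against 10.2 ± 4.90 FPKM. Cyp17a1, the androgen-producing enzyme of theca cells, had 19.8 ± 3.24 against 8.84 ± 7.96, with 20.4 FPKM in melatonin replicate 4 (SD, n = 4 each). Star, which carries cholesterol into mitochondria, had 2.998 ± 0.62 against 2.55 ± 0.065 FPKM. Theca cell markers moved with this group, with 7 of 9 negative (median -0.35; camera adjusted p = 0.0377 and adjusted p = 0.308 with an estimated correlation) and 4 lower adjusted over the list alone. The theca call was lost in 6 of 14 settings (adjusted p from 0.00336 to 0.117). These were quantile normalization (0.066), the filter of 5 FPKM (0.107) and the fits without control replicate 1 (0.0799), control replicate 4 (0.117), melatonin replicate 2 (0.0666) or melatonin replicate 3 (0.0679). Mgarp, a mitochondrial protein of steroid-producing cells, had 43.6 ± 12.5 against 24.5 ± 5.39 FPKM. Luteal markers, which share Cyp11a1, Scarb1 and Lhcgr, among others, with these lists, were lower in 7 of 7 (camera adjusted p = 0.00782 and adjusted p = 0.370 with an estimated correlation), with 2 lower adjusted over the list alone. Without a filter the luteal mean was -0.234 in place of -0.386.

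**Figure D3:**
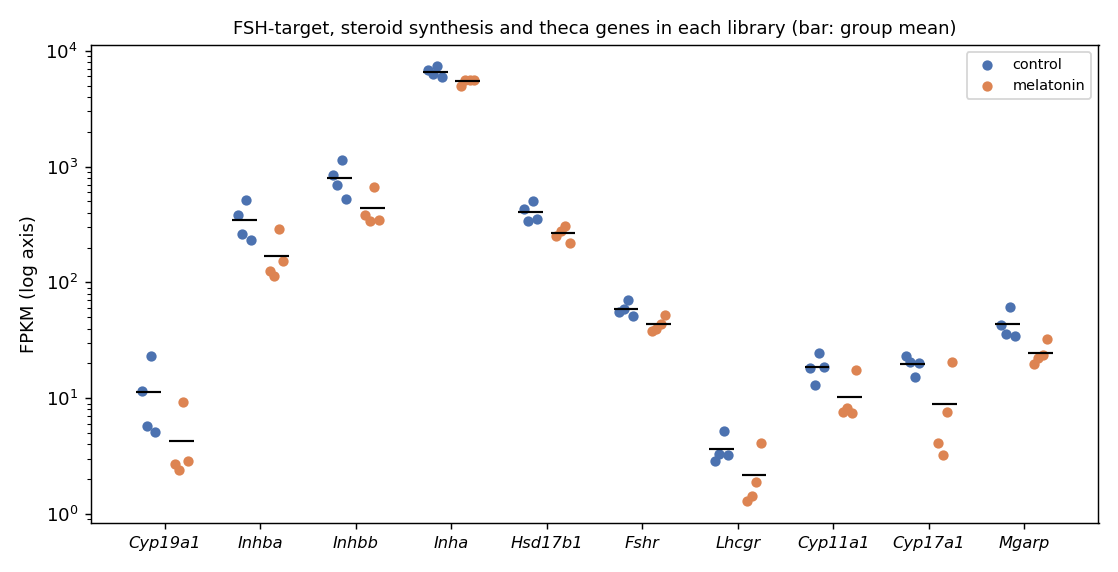
FPKM (log axis) of 10 FSH-target, steroid synthesis and theca genes in each of the 8 libraries, blue for control and orange for melatonin, with a bar at each group mean of 4 libraries. Means were lower with melatonin for each gene shown, for example 347 against 170 FPKM for Inhba, and Cyp17a1 in melatonin replicate 4 (20.4 FPKM) lay among the control values. The genes are a selection. In each of the FSH-target, steroid synthesis and theca lists, 2 tested members had a positive log2 fold change and are not shown.

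Nutrient metabolism lists were lower by camera with the preset correlation. Scores of the groups did not overlap for glycolysis and fatty acid oxidation (exact permutation p = 0.0286 each). They overlapped for cholesterol synthesis (exact permutation p = 0.0571), fatty acid synthesis and amino acid transport (exact permutation p = 0.0857 each). In glycolysis and glucose uptake 22 of 25 members were negative (median -0.28; camera adjusted p = 9.70e-07 and adjusted p = 0.308 with an estimated correlation) and 14 were lower adjusted over the list alone. Pgk1 had 79.9 ± 3.36 FPKM in control and 62.9 ± 5.59 in melatonin and Eno1 59.999 ± 4.37 and 44.3 ± 6.28 (SD, n = 4 each); both are glycolytic enzymes. The glucose transporter gene Slc2a1 had 11.6 ± 1.27 and 10.3 ± 0.90 FPKM (adjusted p = 0.362). Cholesterol synthesis was negative in 22 of 23 (camera adjusted p = 7.84e-06 and adjusted p = 0.412 with an estimated correlation) with 0 past the threshold adjusted over the list alone. Its scores in melatonin replicates 1 to 4 were -0.149, -0.383, 0.094 and -0.079. The mean log2 fold change was -0.258, and -0.174 without melatonin replicate 2, where the call was kept (camera adjusted p = 0.000384). Mvd, an enzyme of the mevalonate pathway, had 10.3 ± 0.87 against 8.18 ± 0.73 FPKM. Amino acid transport was negative in 14 of 19 (camera adjusted p = 0.00489 and adjusted p = 0.333 with an estimated correlation), with 6 lower adjusted over the list alone. These included Slc7a8 (18.7 ± 2.25 against 11.96 ± 2.57 FPKM) and Slc38a5 (174 ± 18.7 against 135 ± 11.9). Fatty acid synthesis and lipid storage was negative in 19 of 27 (camera adjusted p = 0.00771 and adjusted p = 0.417 with an estimated correlation). Its 2 members lower adjusted over the list alone were the desaturase genes Scd1 (2.05 ± 0.24 against 1.21 ± 0.25 FPKM) and Scd2 (414 ± 52.2 against 302 ± 25.9), neighbouring paralogs that can share reads. With the filter of 5 FPKM the call was lost (adjusted p = 0.0922, range 0.00125 to 0.0922). Fatty acid oxidation was negative in 23 of 26 (median -0.10; camera adjusted p = 0.00334 and adjusted p = 0.308 with an estimated correlation), with 0 adjusted over the list alone, and the same filter ended its call (adjusted p = 0.0576, range 0.000466 to 0.0576). Etfa, an electron carrier of this pathway, had 53.7 ± 3.38 against 46.0 ± 2.58 FPKM. Echs1, a hydratase of it, had 12.5 ± 0.83 against 10.98 ± 0.13. Cpt1a, its gatekeeper, had 33.3 ± 4.09 against 31.2 ± 1.68 (adjusted p = 0.612).

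Nuclear genes of oxidative phosphorylation were lower with melatonin in 71 of 72 (median -0.16; camera adjusted p = 1.44e-19 and adjusted p = 0.307 with an estimated correlation). Adjusted over the list alone, 40 were lower, and in 37 the groups did not overlap, where chance gives 2.86% of genes and 11.7% of all tested genes did so. Quantile normalization lowered the size of the mean log2 fold change from -0.162 to -0.097, and for the TCA cycle from -0.124 to -0.079, with both calls kept. The complex I subunit genes Ndufs7 and Ndufs8 had 34.3 ± 0.63 against 28.8 ± 1.22 and 55.5 ± 3.36 against 43.7 ± 3.31 FPKM (SD, n = 4 each). The TCA cycle was negative in 21 of 22 (median -0.13; camera adjusted p = 7.84e-06 and adjusted p = 0.307 with an estimated correlation), with 5 lower adjusted over the list alone. One of these was Mdh2 (46.0 ± 1.196 against 38.7 ± 3.22 FPKM). The 13 genes of the mitochondrial genome did not pass as a list (mean -0.137, camera adjusted p = 0.269), but did in 3 of 14 settings (adjusted p from 0.00394 to 0.881). The list was lower and passed after the GC and length correction (mean -0.26, adjusted p = 0.00394), without control replicate 4 (-0.227, adjusted p = 0.0272) and without melatonin replicate 2 (-0.2095, adjusted p = 0.0456). The mean was -0.034 without melatonin replicate 3 and -0.065 without control replicate 1 or after quantile normalization. mt-Cytb was at 3723 ± 341 against 3309 ± 324 FPKM. mt-Nd4l, which overlaps a neighbour, was at 54.1 ± 23.6 against 33.8 ± 6.82. Mitochondrial biogenesis and dynamics did not pass either (camera adjusted p = 0.298). Of its members 14 of 22 were positive and 1, the fission factor Mff (10.1 ± 0.99 against 12.8 ± 0.50 FPKM), was higher adjusted over the list alone. Its log2 fold change was 0.32, and 0.17 after the GC and length correction. Tfam, the mitochondrial transcription factor, had 9.78 ± 0.64 against 8.37 ± 0.17. Ppargc1a was below the filter at 0.155 ± 0.025 and 0.150 ± 0.059 FPKM. Antioxidant enzymes were negative in 27 of 29 (median -0.13; camera adjusted p = 7.84e-06 and adjusted p = 0.307 with an estimated correlation). Prdx1 (85.8 ± 1.99 against 70.2 ± 5.001 FPKM) and Txn1 (129 ± 4.49 against 110 ± 4.53) were lower adjusted over the list alone.

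**Figure D4:**
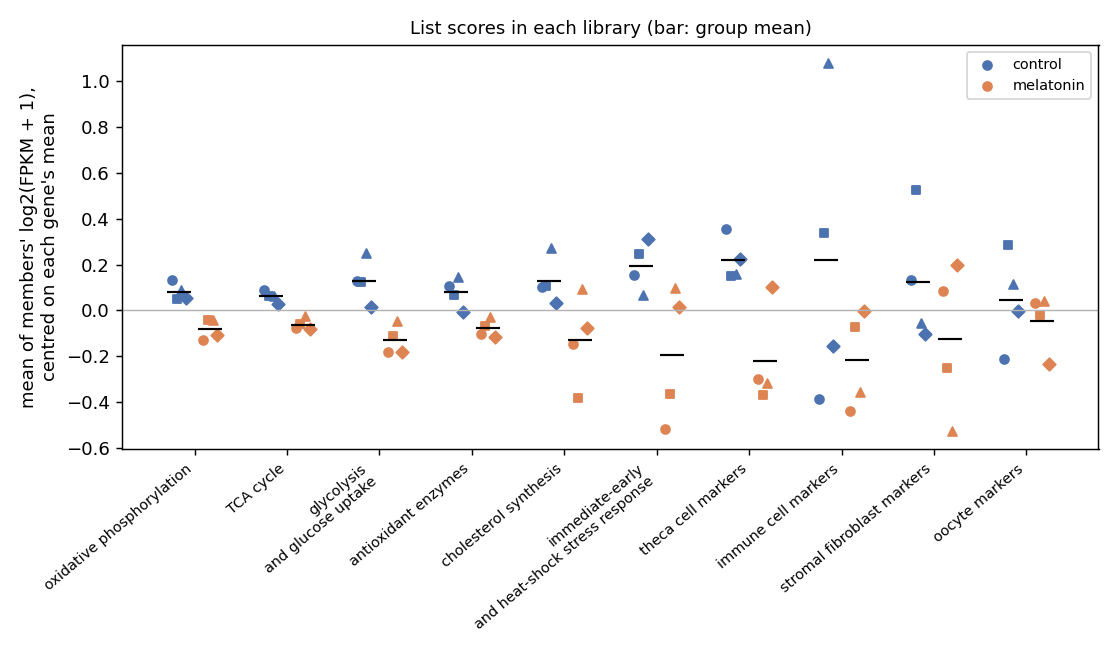
Scores of 10 gene lists in each library (mean over members of log2(FPKM + 1), centred on each gene's mean over the 8 libraries), blue for control and orange for melatonin, marker shape for the replicate number and bars at group means of 4 libraries. Oxidative phosphorylation scores are 0.081 on average in control and -0.081 in melatonin without overlap, while immune cell markers reach 1.08 in control replicate 3.

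Immediate-early and heat-shock genes were lower as a list, with 20 of 24 negative (median -0.43; camera adjusted p = 0.000115 and adjusted p = 0.370 with an estimated correlation). Adjusted over the list alone 8 were lower and 1 was higher, Egr3, named after its values were seen. Klf4 had 5.08 ± 0.75 FPKM in control and 2.66 ± 0.59 in melatonin. Klf2 had 13.5 ± 1.54 and 8.66 ± 1.45, and both are transcription factors (SD, n = 4 each). List scores were -0.52 and -0.37 in melatonin replicates 1 and 2 but 0.096 and 0.015 in replicates 3 and 4. Genes of the cell cycle were negative in 27 of 29 (median -0.18; camera adjusted p = 1.36e-05 and adjusted p = 0.370 with an estimated correlation), with 0 adjusted over the list alone. Mcm7, a replication helicase subunit, had 36.4 ± 2.35 against 31.4 ± 1.91 FPKM. Tyms, thymidylate synthase, had 6.53 ± 0.58 against 5.21 ± 0.56. The unfolded protein response (17 of 20 negative; camera adjusted p = 0.00582 and adjusted p = 0.344 with an estimated correlation) included the chaperones Pdia4 (236 ± 13.1 against 207 ± 3.86 FPKM) and Sdf2l1 (70.3 ± 7.45 against 57.9 ± 1.74), with 0 adjusted over the list alone. The call of this list was lost after quantile normalization (mean -0.05 in place of -0.107, adjusted p = 0.339) and with the filter of 5 FPKM (adjusted p = 0.0757, range 0.00204 to 0.339). In the hypoxia list 10 of 13 were negative (camera adjusted p = 0.0476 and adjusted p = 0.466 with an estimated correlation). There Bnip3 (21.3 ± 2.73 against 16.5 ± 0.89 FPKM) and Egln1 (12.3 ± 0.69 against 10.7 ± 0.47) were lower and Kdm3a, named after its values were seen, was higher adjusted over the list alone. The hypoxia call was lost in 8 of 14 settings (adjusted p from 0.002205 to 0.107), among them quantile normalization, the filter of 5 FPKM and the GC and length correction. It was also lost without control replicate 1 or 3 and without melatonin replicate 2, 3 or 4, and without control replicate 3 the mean was -0.075 in place of -0.119. Apoptosis and atresia genes did not pass (camera adjusted p = 0.352, 13 of 20 negative). Its 2 members past the threshold adjusted over the list alone were higher, Pik3ip1, an inhibitor of PI3 kinase (42.5 ± 6.14 against 59.7 ± 5.23 FPKM), and Ghr, the growth hormone receptor (12.6 ± 1.94 against 20.4 ± 3.60). Ribosomal proteins were negative in 28 of 33 (median -0.08, mean -0.04; camera adjusted p = 0.0016 and adjusted p = 0.547 with an estimated correlation). Rpl13 was at 331 ± 5.59 against 299 ± 3.44 FPKM and Rpl27 was at 313 ± 21.2 against 281 ± 9.83. Their mean turned positive after quantile normalization (0.068, adjusted p = 0.409) and after the GC and length correction (0.0082, adjusted p = 0.0646), where the call was lost. It was positive as well without control replicate 1 or 4, where camera still called the list lower (adjusted p = 0.03998 and 0.0264). The members Rps2 and Rps18, named after their values were seen, were high in those libraries. Rps2 had 148 and 169 FPKM there against 7.73 and 9.70 in the other controls, and Rps18 95.4 and 94.1 against 22.5 and 23.4. Over all settings the mean ranged from -0.094 to 0.068 (camera adjusted p from 3.88e-05 to 0.409). Ribosomal protein genes have processed pseudogenes that can share their reads, so these values are uncertain.

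Oocyte markers did not pass as a list, although 22 of 24 were negative (mean -0.091, camera adjusted p = 0.109). The list passed, lower, without control replicate 1 (mean -0.178, adjusted p = 9.83e-05), without melatonin replicate 1 (-0.117, adjusted p = 0.0326) and without a filter (adjusted p = 0.0375). Its mean was -0.011 without control replicate 2 (adjusted p = 0.979, the highest of the 14 settings) and -0.028 without melatonin replicate 4. Bmp15, an oocyte growth factor, had 38.2 ± 5.01 FPKM in control and 34.5 ± 4.49 in melatonin. Btg4 had 9.85 ± 0.54 and 10.8 ± 0.91, and Kpna7 had 9.01 ± 1.96 and 7.67 ± 0.57 (SD, n = 4 each). Several lists of other cell types passed the test. Surface and oviduct epithelium markers were lower in 9 of 9 (camera adjusted p = 0.00376 and adjusted p = 0.314 with an estimated correlation). The keratins Krt19 (7.03 ± 1.43 against 4.19 ± 0.74 FPKM) and Krt8 (24.7 ± 3.93 against 18.7 ± 2.16) were lower adjusted over the list alone. Immune cell markers were lower in 14 of 14 (camera adjusted p = 0.00943 and adjusted p = 0.547 with an estimated correlation). The list's score was 1.08 in control replicate 3, 0.34 in control replicate 2 and -0.39 in control replicate 1. Without control replicate 3 the mean log2 fold change was -0.149 in place of -0.437 and the call was lost (adjusted p = 0.219, range 9.83e-05 to 0.323). It was also lost without melatonin replicate 3 (adjusted p = 0.0548) and with the filter of 5 FPKM (adjusted p = 0.323). Cd74, a chaperone of antigen presentation, had 6.72 ± 4.91 against 2.51 ± 0.84 FPKM. Cd79a, a B cell receptor component, had 1.55 ± 1.37 against 0.50 ± 0.15. Without control replicate 3 the log2 fold change of Cd74 was -0.57 in place of -0.93 and that of Cd79a -0.31 in place of -0.64. Interferon-stimulated genes were negative in 12 of 15 (camera adjusted p = 0.0115 and adjusted p = 0.466 with an estimated correlation). Isg15 was at 3.29 ± 1.82 against 1.39 ± 0.345 FPKM and Irf7 was at 2.83 ± 0.96 against 1.63 ± 0.275. This call was lost without control replicate 4 (adjusted p = 0.0751) or melatonin replicate 3 (adjusted p = 0.123, range 0.001625 to 0.123), and without control replicate 3 the log2 fold change of Isg15 was -0.51 in place of -0.77. Stromal fibroblast markers were negative in 12 of 13 (camera adjusted p = 0.0342 and adjusted p = 0.547 with an estimated correlation). Col3a1 was at 19.3 ± 6.87 against 13.8 ± 3.68 FPKM and Col6a1 was at 39.1 ± 4.84 against 32.5 ± 7.57. The stromal mean log2 fold change was -0.2495 and went to -0.116 without control replicate 2 (adjusted p = 0.278) and without melatonin replicate 3 (adjusted p = 0.381), where the call was lost. It was also lost without control replicate 1 (adjusted p = 0.0601), without melatonin replicate 2 (adjusted p = 0.0835) and with the filter of 5 FPKM (adjusted p = 0.114, range 0.00126 to 0.381). Endothelial markers (camera adjusted p = 0.0671), among them Sox18 (13.1 ± 1.45 against 9.80 ± 0.50 FPKM) and Egfl7 (2.47 ± 0.46 against 1.77 ± 0.24), did not pass. They passed, lower, in 5 of 13 settings (adjusted p from 0.00606 to 0.302). These were quantile normalization, no filter and the fits without control replicate 4 (adjusted p = 0.0188), melatonin replicate 1 (0.0421) or melatonin replicate 4 (0.0138), while without control replicate 2 the mean was -0.095 in place of -0.16. Smooth muscle and pericyte markers did not either (camera adjusted p = 0.298, with Myl9 at 22.5 ± 5.03 against 16.9 ± 6.72 and Myh11 at 3.19 ± 0.84 against 2.58 ± 0.47 FPKM). Red blood cell markers differed between libraries more than between groups (camera adjusted p = 0.506). Their scores ran from -1.38 to 1.63 among controls, and their mean log2 fold change of -0.236 ranged over the libraries left out from -0.737 without control replicate 1 to 0.268 without control replicate 3. It was -0.532 without control replicate 4 and 0.056 without control replicate 2. Alas2 was at 8.42 ± 6.84 against 4.09 ± 1.52 FPKM and Bpgm at 26.8 ± 3.20 against 24.5 ± 2.43.

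Melatonin's own synthesis and receptor genes were hardly detected. Mtnr1b was listed at 0 in all 8 libraries and Mtnr1a in 7 of 8, where 3 fragments would correspond to between 0.0618 and 0.0937 FPKM depending on the gene and library. Aanat and Asmt, the last enzymes of melatonin synthesis, had 0.264 ± 0.11 against 0.0831 ± 0.032 and 0.164 ± 0.0485 against 0.158 ± 0.098 FPKM (SD, n = 4 each), below the filter, with 35 and 12 recovered fragments per group of 4 libraries for Aanat. Nqo2, a quinone reductase that binds melatonin, was the single tested member of its list, at 5.01 ± 0.25 against 4.81 ± 0.42 FPKM (adjusted p = 0.723). The list of adipose markers had 0 members past the filter. The circadian clock list did not pass (camera adjusted p = 0.401). Of its members 10 of 18 were positive, with Cry1 at 9.77 ± 0.74 against 8.15 ± 0.76 FPKM. Insulin, IGF and PI3K-AKT-mTOR signalling was split 15 to 15 (camera adjusted p = 0.401, median -0.0034, mean 0.04). Its mean was 0.0063 without control replicate 3, 0.022 without melatonin replicate 4 and 0.062 without control replicate 4. Rictor was at 4.92 ± 0.59 against 6.78 ± 0.59 FPKM, Pik3ca at 8.20 ± 0.66 against 9.76 ± 0.40 and Gsk3b at 12.7 ± 0.30 against 12.7 ± 0.55. The GC and length correction took the log2 fold change of Pik3ca from 0.23 to 0.13 and that of Rictor from 0.40 to 0.27. In the cAMP and PKA list 11 of 18 were negative (camera adjusted p = 0.506; median -0.06, mean 0.01), and the mean ranged from 0.0024 without control replicate 3 to 0.029 without control replicate 2 over the libraries left out. Rapgef4, a cAMP-activated exchange factor, was at 17.5 ± 5.79 against 32.9 ± 6.42 FPKM and the cyclase gene Adcy3 was at 6.68 ± 0.75 against 5.27 ± 0.35. Genes of the LH surge and ovulation (camera adjusted p = 0.401, 5 of 8 negative) included Cebpb at 25.0 ± 6.33 against 17.1 ± 2.78 FPKM. Extracellular matrix remodelling did not pass (camera adjusted p = 0.366), with Mmp11 at 87.5 ± 10.6 against 107 ± 12.7 FPKM and Vcan at 25.9 ± 2.55 against 20.5 ± 4.33.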

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

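All tests in this part were chosen after the results were seen. In 15 of 256 groups of 4 libraries, 1 library lay apart from the other 3 by a gap past Dixon's 95% critical value for 4 samples, where chance gives about 1 in 20 groups. Cyp19a1 was at 9.25 FPKM in melatonin replicate 3 (others 2.40 to 2.88) and Inhbb at 673 (others 342 to 385). Cyp11a1 was at 17.5 FPKM in melatonin replicate 4 (others 7.44 to 8.25), and the theca cell marker score there was 0.104 (others -0.368 to -0.301). The circadian clock score was 0.0477 in the same library, and Etfa was at 42.1 FPKM there (others 46.8 to 47.7). Mdh2 was at 43.5 FPKM in melatonin replicate 3 and Inha at 4990 in melatonin replicate 1.

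Among control libraries, replicate 3 had Scarb1 at 35.5 FPKM (others 25.1 to 26.8) and Socs3 at 11.1 (others 13.5 to 13.7). Replicate 2 had Ank at 8.44 FPKM and Col3a1 at 29.5 (others 15.1 to 17.0). Replicate 4 had Gsk3b at 13.2 FPKM and an amino acid transport score of -0.12 (others 0.145 to 0.164). It also had Mtnr1a at 0.0221 FPKM where the others were listed at 0. That value is 1 recovered fragment, and any value above 0 is flagged where the others are all 0.

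The FSH-target and steroid synthesis genes, 26 together, had a score lower by 0.39 with melatonin (difference -0.39, exact permutation p = 0.0286, the smallest the design allows). Steroid synthesis alone also reached that p. The FSH-target list alone did not, as its scores overlapped between the groups (exact permutation p = 0.0571). A trend with GC content or gene length as the whole account is argued against, since the difference was -0.385 after both trends were removed, again at p = 0.0286 by the exact test. Control replicate 3, which had the highest values, leaves part of the difference open: without it the difference was -0.318 (exact permutation p = 0.0571). That p does not come from overlap. The remaining scores were 0.041 to 0.23 in control and -0.351 to -0.028 in melatonin libraries. Fewer theca cells in the melatonin samples could lower Cyp17a1 and Cyp11a1, and 10 FSH targets of granulosa cells, picked after the values were seen, differed by -0.492 with overlap between the groups (exact permutation p = 0.0857). With 4 samples per group a theca share cannot be told apart from a response of granulosa cells. The bound for that test was made stricter after its value was seen, which turned its outcome from against the theca account to open. The score of antisense, sense intronic and TEC transcripts moved the other way between the groups. It was -0.137, -0.102, -0.051 and -0.047 in control replicates 3, 1, 4 and 2, where the FSH and steroid score was 0.43, 0.23, 0.088 and 0.041. In melatonin replicates 4, 1, 3 and 2 it was 0.104, 0.099, 0.069 and 0.064, where the FSH and steroid score was -0.065, -0.351, -0.028 and -0.346, so the inverse order seen in control libraries was not seen there. A difference in RNA handling, an effect of melatonin on FSH-target genes, or follicles collected at slightly different stages stays open and was not tested.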

How the results depend on the processing

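The limma-voom fit, median-ratio scaling, the GC and length correction, the exact test of list scores and the counts over other splits of the samples were chosen after the results were seen. The count of genes with an adjusted p under 0.05 was 0, and stayed 0 under the other settings run except for 1 gene without a filter and 1 without control replicate 1 (range 0 to 1 over the libraries left out). The first was Mir6947 (8 fragments over the control libraries and 0 over the melatonin libraries) and the second C1rb (0.597 FPKM in control replicate 1 and 3.55 to 4.65 in the other controls), both named after their values were seen. At an adjusted p under 0.1 the count was 0, against 203 with a filter of 5 FPKM (fewer genes tested), 318 with array weights, 215 with limma-voom, 169 without control replicate 4 and 70 without melatonin replicate 3. Genes at an unadjusted p under 0.05 numbered 2821 and ranged from 1923 to 3267 over the libraries left out. Of 35 splits of the 8 samples into groups of 4, the real split gave the most such genes (the highest other split gave 2026). A share of 1 in 35 is the smallest the design allows, and other counts were put to the same splits. Chance is therefore argued against for this count but not excluded. For the count of 0 the splits decide nothing, since each of the 35 gives at least 0 (the highest other gave 2).

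The 22 lists called became 0 with an estimated correlation and 0 by the exact test of list scores (where none can pass unless 20 lists reach the smallest p, and 7 did). With fry 5 lists passed (oxidative phosphorylation, TCA cycle, antioxidant enzymes, glycolysis and fatty acid oxidation). Neither fry nor the exact test compares a list with other genes, as camera does, so they answer a different question. The camera calls became 13 with a filter of 5 FPKM, where 30 lists were tested. They numbered 17 to 24 over the libraries left out, 18 after quantile normalization and 21 after the GC and length correction. In 2 of 35 splits the count was as large, the other being controls 1, 2 and 3 with melatonin replicate 4 (22 lists), so chance is not excluded for the list count. Splits with 2 control and 2 melatonin libraries on each side called 1 to 11 lists. The mean of the ribosomal proteins list reversed to 0.0676 after quantile normalization, 0.00819 after the GC and length correction and 0.0130 to 0.0235 without control replicates 4 and 1 (range over the libraries left out -0.0939 to 0.0235), and that of the circadian clock list to -0.00958 with a filter of 5 FPKM. The cause was not tested. The replicate number as a block gave 0 genes, 2776 at an unadjusted p under 0.05 and 22 lists. Same-numbered libraries correlated at 0.0007, -0.10, 0.15 and 0.038 in their deviations from the group means, so the numbers do not pair the samples, and 1 of 4 correlated best with its own number. Of count-based tests, limma-voom alone was run, on the recovered fragment counts and added after the data were seen. The alternatives planned for count tables were otherwise not run, nor was the transcript-level comparison.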

Other observations

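The tests in this part were chosen after the results were seen. Gene families were picked by symbol after the results were seen, so the values describe these libraries and are no independent test. With an estimated correlation none of the 7 families passed (camera adjusted p = 0.266 for potassium channels and 0.0881 for each of the other 6). Log2 fold changes were negative for 36 of 38 proteasome subunits (median -0.19), 74 of 77 mitochondrial ribosomal proteins (median -0.13) and 7 of 7 subunits of the cytosolic chaperonin, which folds actin and tubulin (median -0.14, and -0.06 after quantile normalization). They were positive for 232 of 321 zinc finger proteins named Zfp (median 0.07), 10 of 16 SR splicing proteins and CLK kinases (median 0.10), 18 of 24 lysine methyltransferases and demethylases (median 0.06) and 14 of 24 potassium channels (median 0.12). The sign of each median held after quantile normalization, median-ratio scaling and the GC and length correction, but some shrank by over 1.5 times. The GC and length correction took the SR and CLK median to 0.061 and that of the lysine enzymes to 0.042, and quantile normalization took the Zfp median to 0.044 and that of potassium channels to 0.078. The score difference of potassium channels was 0.011 (exact permutation p = 0.857) and turned to -0.015 after quantile normalization.

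Several classes of transcripts not annotated as protein-coding were higher with melatonin, and others were not. Of 241 transcripts of the TEC class (gene models awaiting experiments), 206 had a positive log2 fold change (median 0.23), 69 of them at an unadjusted p under 0.05 and higher against 1 lower. Antisense transcripts were higher in 291 of 394 (median 0.13), long intergenic RNAs in 223 of 336 (median 0.10) and processed transcripts in 101 of 140 (median 0.11). Sense intronic transcripts were higher in 43 of 53 (median 0.16), and in 35 of 53 after the GC and length correction (median 0.10). Each of these 5 class scores separated the 4 melatonin from the 4 control libraries (exact permutation p = 0.0286, the smallest possible, and 0.0357 adjusted over 10 classes), also after the GC and length correction. Small nuclear RNAs (median 0.28) and microRNAs (median 0.13) did so before that correction and not after it (exact permutation p = 0.114 and 0.886). Small nucleolar RNAs did not pass (exact permutation p = 0.257), and their score difference turned from 0.047 to -0.085 after the correction. Processed pseudogenes, of which 347 of 834 were positive (median -0.04), did not pass either (exact permutation p = 0.257). Protein-coding genes had a median of -0.02 and a score difference of -0.017 (exact permutation p = 0.0286), which no longer separated the groups after median-ratio scaling (-0.011, exact permutation p = 0.171). Most of the 10 classes stood at the smallest exact permutation p before the GC and length correction. That p therefore adjusts to 0.0357 here and to 0.139 over the 34 lists. FPKM is relative to the other genes of a library, so the classes are not independent of each other.

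The antisense, intronic and TEC classes together held 688 transcripts, whose mean was 3.06 ± 0.14 FPKM in control and 3.55 ± 0.081 in melatonin (SD, n = 4 each; exact permutation p = 0.0286). Genomic DNA in the libraries is argued against, since it would raise silent loci as well and the mean of 1978 silent olfactory and vomeronasal receptor genes differed by -2.99e-05 FPKM where the class differed by 0.486. The bound for that test was rewritten after its value was seen, with the same outcome. Neither trends of GC content and length nor control replicate 3 alone account for the score difference of 0.168: it was 0.156 after the GC and length correction and 0.150 without that library, both at an exact permutation p of 0.0286. The use of strand is not given in the sources used here, so reads of unspliced host transcripts could be counted in these classes, and a larger unspliced share of RNA in the melatonin samples, from the treatment or from the handling of the tissue, stays open and was not tested.

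A few ribosomal protein genes and processed pseudogenes differed widely between libraries of the same group. Rpl29 was at 136 and 134 FPKM in melatonin replicates 1 and 3 and at 5.24 and 6.59 in replicates 2 and 4, and Rps2 at 148 and 169 in control replicates 1 and 4 and at 7.73 and 9.70 in replicates 2 and 3, both picked after their values were seen. Of 916 tested genes of these kinds, 36 were among the 148 genes with the largest spread within groups (24.3% of these 148, against 6.22% of all tested genes; p = 7.96e-13 by Fisher's exact test across genes, which are not independent). Reads shared between near-identical copies could give this, as reads would then pass from 1 copy to another and the sum of a family would vary less than its members. In 8 families with such a member the variance of the sum was 0.608 of the summed variances (median), and under 1 in 6 of the 8, which leaves this open. The test was first run over all 42 families, where the median was 1.01, and was narrowed to the 8 after that value was seen. Sequence variants of the outbred Kunming stock against the reference were not tested.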
